A study of Mus musculus with 9 samples.

How the data were processed

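Expression was measured in 9 mouse TS cell lines, each hybridised to 1 single-colour array. The authors deposited 1 table of 45101 probe sets, whose values are intensity signals on a linear scale made with MAS5, per the submitters' processing notes, which give no version. MAS5 combines the probes of a probe set into 1 signal after subtracting a background estimated from mismatch probes, so that low signals are noisy. The scaling target, the background settings and the detection calls are not given in the sources used here. The 2% trimmed mean of the deposited signals ranged from 76.8 to 129 between arrays, a ratio of 1.68, so the arrays did not share a scaling target. Deposited signals ranged from 0.045 to 13782.

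The 64 control probe sets were left out, which leaves 45037. Each array was scaled to the same trimmed mean, and the values were analysed as log2(signal + 5.53), the added value being the 25th percentile of all signals. A fold change is therefore on the scale of signal plus this value and understates the change of dim genes. Probe sets were kept when their mean log2 value over all 9 arrays lay above the 40th percentile (4.00, a signal of 10.5), which left 27022. Gene names came from the platform's annotation. Of the 45037 probe sets, 34945 named 1 gene, 932 named several and 9160 had no name there, and no gene was named from a probe set with several. Symbols were updated through Entrez identifiers in a RefSeq gene table, in which 34741 of the single-gene probe sets were found. That table is of assembly GRCm38.p6 and served for names and for X and Y linkage only. For tests by gene, the probe set with the highest mean signal stood for its gene, which gave 12231 genes. No reference genome was used here, and no coordinates are given.

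A linear model with 4 group means was fitted over all 9 lines with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 5 residual and 5.96 prior degrees of freedom. Contrasts were two-sided: nuclear transfer minus native, averaged over backgrounds and within each, the difference between these, and CD-1 minus BDF1, averaged over origins and within each. P-values were adjusted by the Benjamini-Hochberg method over all probe sets for counts and over all genes for named genes, with a threshold of 0.05. Values after ± are standard errors of the fit unless stated otherwise. Line numbers were taken as names of separate lines. Jsonlite 2.0.0 read the labels, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

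Before the data were examined, 23 gene lists were fixed for trophoblast and other cell types, imprinting, X and Y linkage and pathways, and the design, the alternatives and the rule for named genes were chosen too. Lists were tested for origin, background and their interaction with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma, adjusted over 23 lists. The Y-linked list, with 2 measured genes, was given by gene only, and all X-linked genes formed a further list. Fry asks whether the genes of a set move on balance 1 way and does not compare them with other genes. In 13 of 69 list tests the median, the mean and the test differed in sign, and none of these passed. The rule named, for origin and for background, the 12 higher and 12 lower genes with the largest difference among those that passed with the same direction on both sides of the other factor. Where fewer than 20 passed, it added genes whose lines did not overlap, by smallest p, up to 24. It added up to 4 members per list that passed over the list alone and 22 check genes, and for other contrasts up to 6 genes per direction. Genes outside the rule are named as chosen after their values were seen, or as examples within a list.

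The fit was tested on simulated data for all 27022 probe sets, with 200 changed, in 10 repeats. With spreads drawn from the fitted prior, 25.5% of changes of 1 log2 unit and 70.9% of those of 2 were recovered for origin, and 5.12% of calls were false. For background these were 26.6%, 75.0% and 4.60%. With the moderated spreads of the real probe sets, 34.6% and 82.3% were recovered for origin with 7.00% false calls, and 37.6% and 85.1% for background with 7.95% false calls, which exceeds the nominal share. Moderated spreads are already drawn towards the fitted trend, and for origin the simulated data gave 10.0 prior degrees of freedom, against 5.96 in the real data. Recovery with these spreads may therefore be too high. All values were drawn independently, with the same spread in each line, so deviations that many genes share in a line were not simulated. The shares of false calls hold for such simulated data only.

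Alternatives covered the pseudocount, the filter, quantile normalization and median centring, the variance model, array weights, an additive model, the other factor left out, the line number as a block, and a covariate of Y-linked signal. They also covered leaving out genes on the X and Y chromosomes, leaving out less specific probe sets, the mean over probe sets, each line left out in turn and the set test.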

Results

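Messenger RNA was measured on Affymetrix oligonucleotide arrays in 9 mouse trophoblast stem (TS) cell lines, with 1 array per line. TS cells are the self-renewing precursors of the placental trophoblast and are kept undifferentiated in culture by fibroblast growth factor (FGF). Of these lines, 4 came from native blastocysts and 5 from blastocysts made by somatic cell nuclear transfer, in which the nucleus of a body cell replaces that of the egg. Both kinds were derived on BDF1, a hybrid laboratory background, and on CD-1, an outbred stock that carried an EGFP transgene here. The groups held 2 native and 3 nuclear transfer lines on BDF1, and 2 native and 2 nuclear transfer lines on CD-1. Embryos were taken at day 3.5 and cells were collected on culture day 4, in medium with 25 ng/ml bFGF and 20% serum. The deposited signals had trimmed means between 76.8 and 129 per array, and each array was scaled to a common value of 101. The number of arrays limits the precision, and p-values measure the spread between these lines, which includes any variation between single arrays. The median standard error of a log2 difference was 0.26 for origin averaged over both backgrounds.

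The undifferentiated state was examined first in each line. The TS cell transcription factors Eomes and Elf5 had signals of 312 to 1163 and of 870 to 2258 over the 9 lines, and Tfap2c of 502 to 1858. Cdx2, which specifies trophectoderm, lay between 90.4 and 364, and the nuclear receptor Esrrb between 113 and 813. CD-1 native line 1 gave the lowest value of Cdx2, Eomes, Elf5 and Esrrb. Fgfr2, the FGF receptor of TS cells, lay between 315 and 642, and Hand1, a factor of trophoblast giant cells, between 316 and 1230. None of these 7 genes passed for origin in limma, with log2 differences between −0.09 ± 0.16 for Fgfr2 and 0.84 ± 0.40 for Esrrb (± standard error of the fit, n = 5 and 4 lines) and adjusted p from 0.51 to 0.90. Without CD-1 native line 2, which left a lone line in its group, the Esrrb difference was 1.47. The pluripotency factor Pou5f1 and the spongiotrophoblast gene Tpbpa were below the signal filter. The endoderm factor Gata6 stayed at or under 44.1 and the fibroblast collagen Col1a1 at or under 24.6, and neither passed for origin (0.44 ± 0.28, adjusted p = 0.67, and 1.21 ± 0.34, adjusted p = 0.37). Log2 values of the tested Col1a1 probe set, which were low, were nevertheless higher in each nuclear transfer line. They were 4.61 to 4.91 against 2.67 and 3.18 in BDF1, and 4.37 and 4.62 against 3.97 and 3.87 in CD-1. Another Col1a1 probe set, below the filter, overlapped between origins. Its values were 2.74 to 3.33 against 2.63 and 2.94 in BDF1, and 2.92 and 3.11 against 4.03 and 2.98 in CD-1. Prl3d1, Gcm1, H19 and Ddx3y had no probe set that named them alone and were not analysed here.

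Lines of 1 background resembled each other more than lines of different backgrounds. Across the 27022 probe sets tested, pairs of lines that shared background and origin had a mean Pearson correlation of 0.938 (6 pairs). It was 0.935 for pairs sharing the background alone, 0.931 for pairs sharing the origin alone and 0.926 for pairs sharing neither (10 pairs each). The mean for pairs of 1 background exceeded that for pairs of different backgrounds by 0.00671, and 3 of the 126 ways to split the lines into 4 and 5 gave as large a value (one-sided exact permutation p = 0.0238, adjusted p = 0.0476 over 2 tests). For origin the excess was 0.00321, reached by 14 of 126 splits (one-sided exact permutation p = 0.111, adjusted p = 0.111). CD-1 native line 1 stood apart, with a mean correlation with the other lines of 0.917, against 0.925 to 0.939 for the others. Its score on the first principal component, which held 22.0% of the variance, was 85.6, against −54.4 to 17.9.

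The comparison by origin asked how TS cells from nuclear transfer embryos differ from those of native embryos. Averaged over both backgrounds, nuclear transfer lines had lower signals for epithelial junction genes and for interferon and antigen presentation genes, and higher signals for FGF-responsive genes and for genes of the unfolded protein response. These 4 lists passed at a preset correlation between genes, and none did with the correlation estimated (adjusted p = 0.33, 0.33, 0.43 and 0.31 with an estimated correlation), and the FGF difference came mostly from CD-1 native line 1, without which its median was 0.19 and not 0.67. The estimated correlation was 0.41 for the epithelial, 0.47 for the interferon, 0.48 for the FGF and 0.02 for the unfolded protein list, against a preset of 0.01. P-values at the preset treat the genes of the first 3 lists as nearly independent and may be far too small. Most single genes did not pass the test over all genes. Xist, the noncoding RNA that coats the inactive X chromosome, was higher (log2 difference 3.72 ± 0.19, adjusted p = 6.5e-06), and Eif2s3y, a Y-linked translation factor subunit, was lower (−2.90 ± 0.30, adjusted p = 0.0070). Both differences came from the CD-1 lines, and their size depends on the pseudocount, since the lower signals lay under the signal filter. Tmem87a, which encodes a membrane protein, was the remaining gene that passed (−1.79 ± 0.22, adjusted p = 0.023), with differences of 0.17 in BDF1 and −3.76 in CD-1.

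Counted by probe set, 7 of 27022 passed for origin at an adjusted p under 0.05 in limma, 3 higher and 4 lower, and 2176 had an unadjusted p under 0.05 where 1351 are given by chance. The number was 38 without CD-1 native line 2 and 3 without CD-1 nuclear transfer line 5, and it was 0 when the interaction term or the background was left out of the model or a covariate of Y-linked signal was added, and 2 without an intensity trend. All 7 also passed within CD-1, where their log2 differences had sizes of 2.54 to 7.43, against −0.85 to 0.42 in BDF1. They were 2 probe sets of Xist, 1 each of Eif2s3y, Tmem87a and the proteasome subunit gene Psmd6, chosen after its values were seen, and 2 without a gene name.

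The epithelial list fixed before the data were examined had 22 measured genes, of which 21 were lower in nuclear transfer lines, with a median log2 difference of −0.38. Adjusted over the list alone, 8 fell: Spint1 and Spint2, which encode membrane inhibitors of serine proteases, by 1.61 and 0.67, the claudin genes Cldn6 and Cldn3 by 0.96 and 0.88, and the epithelial transcription factor Grhl2 by 0.69, with Tjp1, Dsc2 and Dsp. Over all 12231 genes none passed, with 12 of the 22 at an unadjusted p under 0.05 in limma. The simple-epithelium keratins did not pass, with differences of −0.07 ± 0.19 for Krt8 and −0.10 ± 0.14 for Krt18. Against other genes the list was lower with an adjusted p of 9.4e-09 at a preset correlation (limma camera). It did not pass with the correlation estimated from these lines, at an adjusted p = 0.33 with an estimated correlation. By line, its mean deviation from the average was 0.92 in CD-1 native line 1, 0.50 in CD-1 native line 2, 0.45 in BDF1 native line 2 and −0.54 in BDF1 native line 1. The nuclear transfer lines lay between −0.59 and −0.05. Without BDF1 native line 1, the native line with a negative deviation, the Spint1 difference was −1.97.

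Of 22 interferon and antigen presentation genes, 20 were lower in nuclear transfer lines, with a median of −0.90. Adjusted over the list alone, 5 fell: the class I histocompatibility genes H2-D1 (−1.60 ± 0.36) and H2-K1 (−0.92 ± 0.25), and the interferon-stimulated genes Usp18 (−3.14 ± 0.85), Ifitm3 (−2.04 ± 0.57) and Oasl2 (−2.17 ± 0.64). None passed over all genes in limma, with 12 at an unadjusted p under 0.05. The list's adjusted p was 3.1e-09 with camera's preset, and it did not pass with an adjusted p = 0.33 with an estimated correlation. Ifitm3 had a signal of 420 to 496 in the 4 native lines and of 30.0 to 121 in the nuclear transfer lines other than CD-1 line 3, which had 443. The mean deviation of this list was 0.26 and 0.93 in the BDF1 native lines and 1.27 and −0.19 in those of CD-1. In nuclear transfer lines it was −0.43, −0.33 and −0.997 in BDF1 and 0.24 and −0.75 in CD-1, so that the origins overlapped. Without CD-1 native line 1, the highest, the median was −0.51. Without CD-1 nuclear transfer line 3, where Ifitm3 was in the native range, its difference was −2.95. That of Usp18 was −4.13 without CD-1 native line 2, which left the list's highest line alone in its group.

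Of 21 genes that respond to FGF and ERK signalling, 18 were higher in nuclear transfer lines, with a median of 0.67. There were 5 that rose when adjusted over the list alone: the transcription factors Fosl1 (1.33 ± 0.30) and Myc (0.90 ± 0.27), the ERK phosphatase Dusp5 (1.01 ± 0.29), and the pathway inhibitors Spry2 (0.96 ± 0.29) and Spred2 (0.82 ± 0.26). None passed over all genes in limma, with 7 at an unadjusted p under 0.05. The list had an adjusted p of 3.4e-06 with camera's preset, and an adjusted p = 0.43 with an estimated correlation. Its mean deviation was −1.39 in CD-1 native line 1 and between −0.24 and 0.48 in the other 8 lines. The TS stem state list was also lowest in that line, at −0.68 against −0.00068 to 0.21 in the others. Without that line the median was 0.19. Without CD-1 native line 2, which left CD-1 native line 1 alone in its group, the differences of Fosl1 and Spry2 were 1.76 and 1.40.

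Of 22 genes of the unfolded protein response, 15 were higher, with a median of 0.24. Adjusted over the list alone, 5 rose: Psat1 (0.66 ± 0.13) and Asns (0.65 ± 0.15), enzymes of serine and asparagine synthesis, the stress transcription factor Atf4 (0.75 ± 0.18), and Trib3 (1.45 ± 0.38) and Chac1 (1.20 ± 0.36), which it induces. The endoplasmic reticulum chaperones Hspa5 (0.07 ± 0.10) and Hsp90b1 (0.11 ± 0.13) did not pass. None passed over all genes in limma, with 5 at an unadjusted p under 0.05. Atf4 did without BDF1 nuclear transfer line 2 (0.90). The list had an adjusted p of 0.0026 with camera's preset and an adjusted p = 0.31 with an estimated correlation.

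**Figure D1:**
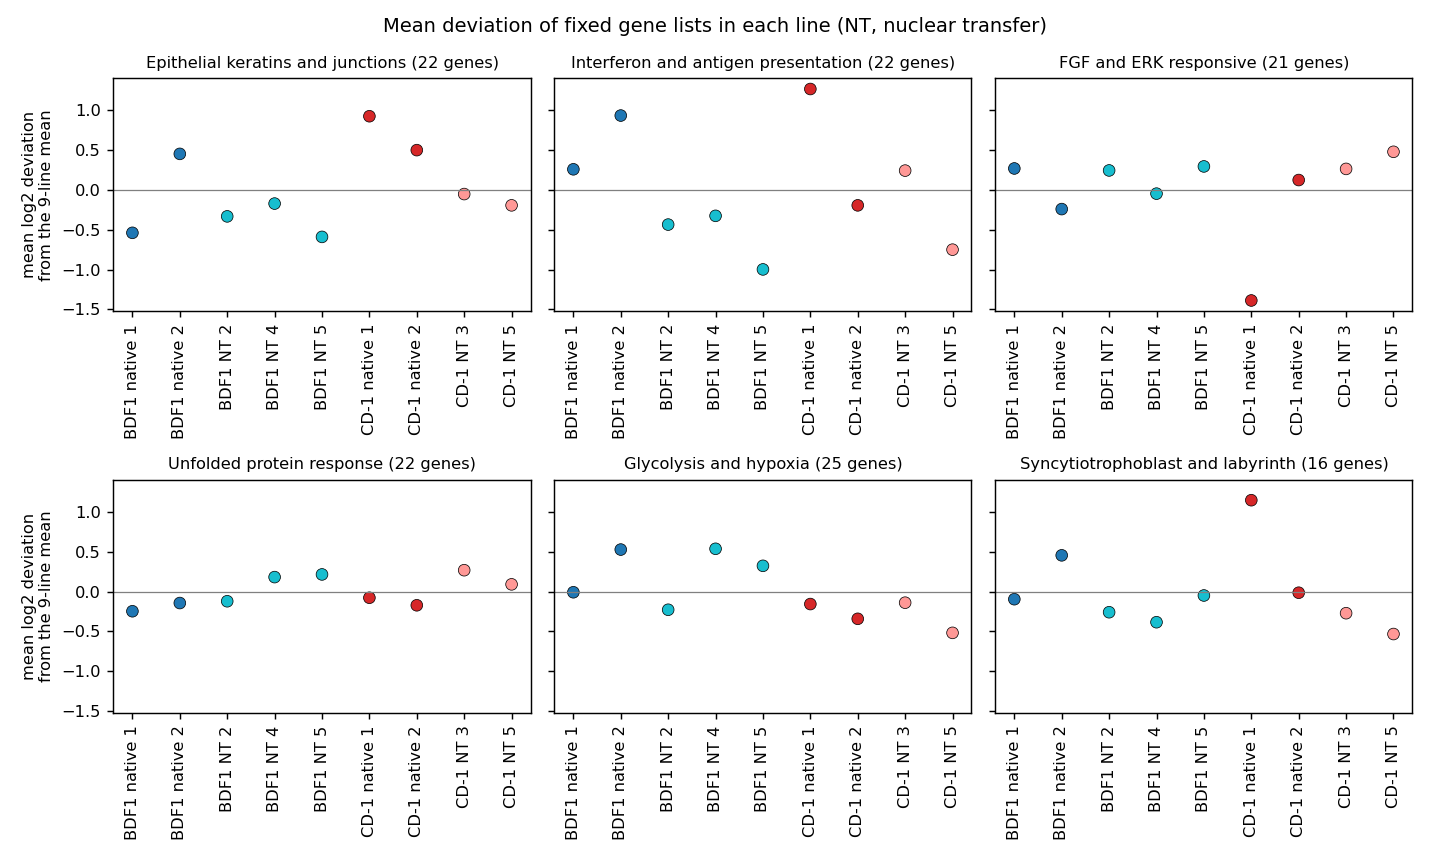
Mean log2 deviation from the 9-line mean (vertical axis) of 6 fixed gene lists in each TS cell line (horizontal axis), 1 point per line, coloured by group. The FGF and ERK list is at −1.39 in CD-1 native line 1 and between −0.24 and 0.48 in the others, and that line also has the highest epithelial, interferon and syncytiotrophoblast values.

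Among lists of placental cell types, that of syncytiotrophoblast and labyrinth was lower in nuclear transfer lines in 14 of 16 genes (median −0.73, adjusted p = 1.1e-04 with camera's preset and adjusted p = 0.31 with an estimated correlation). With a covariate of Y-linked signal its median was −0.11 and the set test turned upward (adjusted p = 0.94). That fit cannot tell whether Y-linked signal accounts for the difference, since the covariate's slope came only from differences within groups. No member passed over the list alone in limma, with 5 at an unadjusted p under 0.05. Its mean deviation was highest in CD-1 native line 1 (1.15). The lists of the TS stem state (16 of 23 genes higher, median 0.26, adjusted p = 0.092), trophoblast giant cells (6 of 13 higher, −0.05, 0.94) and spongiotrophoblast and glycogen cells (4 of 10 higher, −0.14, 0.43) did not pass. Neither did those of fibroblasts (−0.12, adjusted p = 0.94), embryonic stem cells (0.04, 0.86), endoderm (−0.13, 0.97) and cumulus or granulosa cells (8 of 8 genes lower, −0.29, 0.17). The remaining lists that did not pass were TGF-beta (median −0.36, adjusted p = 0.23), DNA methylation and chromatin silencing (−0.07, 0.62), germline genes (−0.25, 0.35), cell cycle (−0.09, 0.23), glycolysis and hypoxia (−0.09, 0.77), cholesterol synthesis (0.01, 0.77) and all 380 X-linked genes (0.04, 0.86). From the glycolysis and hypoxia list, the angiogenic factor Vegfa rose by 0.79 ± 0.18, adjusted over the list alone. The p53 list was lower in 16 of 18 genes (median −0.17, adjusted p = 0.028, and adjusted p = 0.47 with an estimated correlation). Its call ended without BDF1 native line 1 (median −0.12), BDF1 nuclear transfer line 5 (−0.08), CD-1 native line 2 (−0.20) or CD-1 nuclear transfer line 5 (−0.14).

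Of 27 imprinted genes expressed from the maternal allele, 19 were lower in nuclear transfer lines, with a median of −0.21 (adjusted p = 0.0026 with camera's preset, adjusted p = 0.31 with an estimated correlation). The preset call ended without CD-1 nuclear transfer line 5 (median −0.24). There were 2 that fell when adjusted over the list alone: Phlda2, a restrainer of placental growth, by 1.94, and Cd81, a tetraspanin, by 0.91. The list of 24 genes expressed from the paternal allele did not pass (9 higher, median −0.23, adjusted p = 0.73). Cdkn1c, a growth-restraining cell cycle inhibitor, and Peg3 did not pass for origin (−0.59 ± 0.27, adjusted p = 0.54, and 0.13 ± 0.16, adjusted p = 0.85). Igf2, the growth factor of the fetus and placenta, had a difference of −2.15 ± 0.89 (adjusted p = 0.51), with signals of 197 in BDF1 nuclear transfer line 5 and 354 in CD-1 nuclear transfer line 3, against 2887 to 6753 in the other lines. Meg3, a maternally expressed noncoding RNA, had signals of 1565 in CD-1 nuclear transfer line 3 and 553 in BDF1 native line 1, and of 15.8 to 42.4 in the others (difference 0.28 ± 1.08, adjusted p = 0.96). Grb10 and Igf2r, chosen after their values were seen, also differed strongly between lines of a group. The growth-inhibiting adaptor Grb10 had 113 and 132 in BDF1 nuclear transfer lines 2 and 4 and 86.4 in CD-1 nuclear transfer line 3, against 1551 to 3456 elsewhere. Igf2r, the receptor that clears IGF2, had 60.9 and 69.4 in BDF1 nuclear transfer lines 2 and 4, against 571 to 921 elsewhere.

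**Figure D2:**
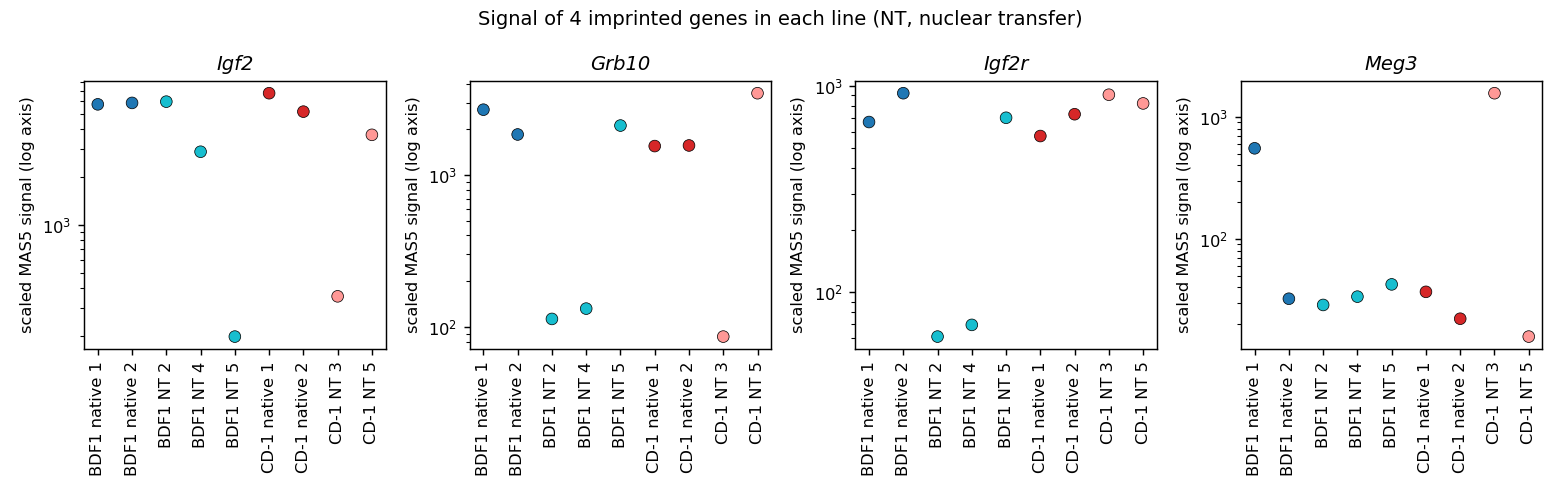
Scaled signal (vertical axis, log scale) of 4 imprinted genes in each TS cell line (horizontal axis), 1 point per line, coloured by group. Igf2 is low in 2 nuclear transfer lines, Grb10 in 3 and Igf2r in 2, while Meg3 is high in 1 native and 1 nuclear transfer line.

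Among the genes whose nuclear transfer and native lines did not overlap on either background, in the same direction, none of the 22 named by the rule passed. Of all 12231 genes, 588 had such a separation, where chance gives 3.33% (408 genes). Those with the smallest p were Tmem30b, a subunit of lipid flippases (−1.80 ± 0.26, adjusted p = 0.079), the nucleolar gene Mybbp1a (0.63 ± 0.09, 0.079) and Syne4, which links the nucleus to kinesin (−1.27 ± 0.20, 0.11). The largest lower differences were −2.66 ± 0.50 for the Rho GTPase-activating Arhgap8 and −1.84 ± 0.41 for the kinase gene Rps6ka6. Tmem54, Parm1, Tbx20, Galnt3, Bcam, Nrtn, Tmem159, Unc13b and Rhbdf1 were also lower, between −1.70 and −0.63. On the higher side were Ptprcap (1.88 ± 0.33) and the thromboxane receptor Tbxa2r (1.58 ± 0.31), followed by Slc1a4, a serine and alanine transporter (1.01 ± 0.21), the mitochondrial folate enzyme Mthfd2 (0.89 ± 0.17), Rai14, Psat1, Ifrd1 and Pgm2. Their adjusted p lay between 0.079 and 0.27. Without CD-1 native line 2, which left a lone line in its group, the differences of Tmem30b, Mybbp1a and Syne4 were −1.85, 0.62 and −1.32. Without BDF1 nuclear transfer line 2, Mthfd2 passed (1.00).

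Within BDF1, 3 nuclear transfer lines were set against 2 native lines, and the same genes showed no difference that passed. Xist had 1417 and 2166 in the native and 1639 to 1926 in the nuclear transfer lines (log2 difference 0.01 ± 0.25). By limma 0 of 27022 probe sets passed, the smallest adjusted p was 0.60, and 1336 had an unadjusted p under 0.05 where 1351 are given by chance. The count was 2 without BDF1 nuclear transfer line 5, and 1 without BDF1 native line 2 or BDF1 nuclear transfer line 4.

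Within CD-1, Xist was far higher in the nuclear transfer lines than in the native lines. Xist had signals of 1317 and 1670 in the nuclear transfer lines and 5.35 and 1.28 in the native lines (log2 difference 7.43 ± 0.27, adjusted p = 2.5e-07), where the native values lie under the signal filter of 10.5. A further Xist probe set read 769 and 1006 against 15.9 and 27.5, above that filter. Eif2s3y showed the opposite, with 8.08 and 5.20 against 411 and 331 (−4.95 ± 0.45, adjusted p = 0.0011). The X inactivation and escape list was higher in nuclear transfer lines on average over backgrounds in 10 of 11 genes (median 0.21, adjusted p = 0.0010 with camera's preset and adjusted p = 0.27 with an estimated correlation), and fry, which tests whether the genes move 1 way, gave an adjusted p of 0.0059. Adjusted over the list alone, Xist, the histone demethylase gene Kdm6a (0.63 ± 0.20) and Utp14a (0.52 ± 0.16) rose on this average. No set test of this list was run without Xist, so how far the set results rest on Xist is not shown. Of the Y-linked list, 2 genes were measured, and Uba1y did not pass, with −0.14 ± 0.48 within CD-1 and 0.33 ± 0.32 on average over backgrounds. Within CD-1, Tmem87a was lower, at 16.5 and 5.61 against 230 and 185 (−3.76 ± 0.33, adjusted p = 0.0011). In all, 16 probe sets passed within CD-1, 5 higher and 11 lower, and 2348 had an unadjusted p under 0.05. The count was 101 without CD-1 native line 2, 7 without CD-1 nuclear transfer line 5 and 10 without BDF1 nuclear transfer line 2. It was 6 without an intensity trend, 28 with robust variances and 0 with the covariate of Y-linked signal.

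**Figure D3:**
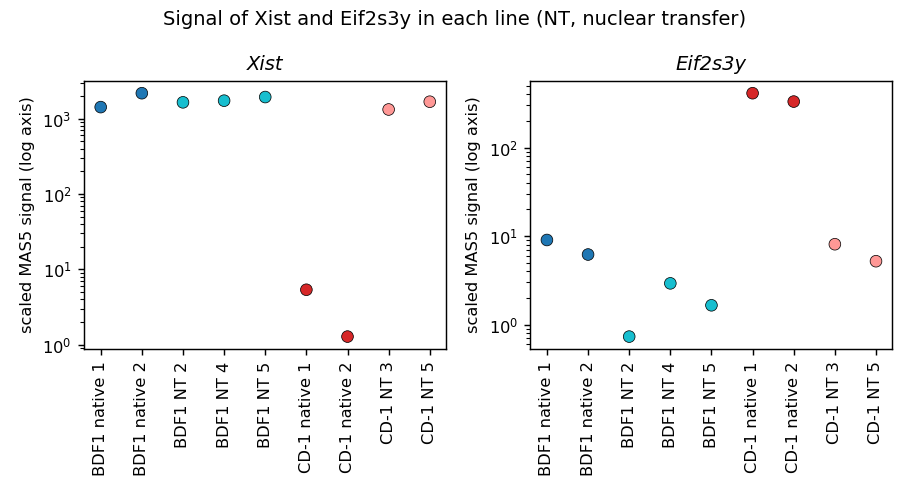
Scaled signal (vertical axis, log scale) of Xist and Eif2s3y in each TS cell line (horizontal axis), 1 point per line, coloured by group. The 2 CD-1 native lines have Xist at 5.35 and 1.28 and Eif2s3y at 411 and 331, while the other lines have Xist between 1317 and 2166 and Eif2s3y at or under 9.03.

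The origin difference itself differed between backgrounds for 4 probe sets of 3 genes. The interaction was 7.43 ± 0.37 and 5.67 ± 0.40 for Xist, −3.93 ± 0.44 for Tmem87a and −3.14 ± 0.31 for Psmd6, with 1676 probe sets at an unadjusted p under 0.05. The count was 8 without CD-1 native line 2, and 2 when genes on the X and Y chromosomes were left out. Over all genes the adjusted p of Tmem87a was 0.014, and it lay between 0.055 and 0.17 without either BDF1 native line, any of the BDF1 nuclear transfer lines or CD-1 native line 1. A second probe set of Psmd6 differed by 0.14 within CD-1. Over all genes, the origin differences in BDF1 and in CD-1, which share no lines, correlated with r = 0.125 across genes and had the same sign in 53.1%. Genes are not independent replicates. Of the lists, FGF and ERK (median 0.87, adjusted p = 0.0015), TGF-beta, nodal and activin (0.66, 0.013) and epithelial genes (−0.54, 0.0065) passed with camera's preset. None did with the correlation estimated (adjusted p = 0.71, adjusted p = 0.68 and adjusted p = 0.71 with an estimated correlation). No member passed over these lists alone. Without CD-1 native line 1 the medians were 0.20, 0.52 and −0.44, and without BDF1 native line 1 they were 0.69, 0.56 and −0.05, and in both cases none of the 3 passed. With a covariate of Y-linked signal the TGF-beta median was −1.37. The TGF-beta call also ended without BDF1 native line 2 (0.77) or BDF1 nuclear transfer line 5 (0.48). The other 20 lists had adjusted p between 0.0508 and 0.997. The number of passing lists was 6, 6, 7, 10, 8 and 7 without BDF1 native line 2, BDF1 nuclear transfer lines 2 and 4, CD-1 native line 2, and CD-1 nuclear transfer lines 3 and 5, and 1 without either BDF1 or CD-1 native line 1.

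The comparison by background, CD-1 against BDF1 averaged over origins, gave the most calls. CD-1 lines had higher signals of the heparan sulfate proteoglycan Sdc4 (3.39-fold, log2 difference 1.76 ± 0.16, adjusted p = 9.4e-04), of Tfap2c (2.25-fold, 1.17 ± 0.21, adjusted p = 0.046) and of Tex19.1, a gene of germ cells and placenta (1.82-fold, 0.87 ± 0.14, adjusted p = 0.038). They had lower signals of Rpgrip1, a ciliary protein gene (−2.86 ± 0.13, adjusted p = 1.7e-06), and of Id1, an inhibitor of helix-loop-helix factors (−1.39 ± 0.19, adjusted p = 0.012). In each case where a gene had other probe sets these differed less, by 0.08 for Sdc4, a median of 0.18 for Tfap2c and 0.22, in the opposite direction, for Rpgrip1. Glycolysis and hypoxia genes were lower and epithelial genes higher as lists at a preset correlation, but not with adjusted p = 0.61 and adjusted p = 0.67 with an estimated correlation. Each value compares 4 CD-1 with 5 BDF1 lines. The calls of Sdc4 and Rpgrip1 held without any 1 line, while those of Tfap2c and Tex19.1 rested on nearly all lines: without CD-1 nuclear transfer line 3, for example, their adjusted p were 0.13 and 0.12.

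By limma 97 probe sets passed, 36 higher and 61 lower, with 2695 at an unadjusted p under 0.05, and by gene 41 of 12231 did, 20 higher and 21 lower. The probe set count was 34 without an intensity trend in the variances, 64 in an additive model, 19 with the mean over probe sets of a gene and 0 with a covariate of Y-linked signal. With lines left out, it was 167 without CD-1 native line 2. It fell to 41 without CD-1 nuclear transfer line 5, 43 and 60 without BDF1 native lines 1 and 2, 61, 48 and 58 without BDF1 nuclear transfer lines 2, 4 and 5, and 59 without CD-1 nuclear transfer line 3. Of the 97 probe sets, 57 had other tested probe sets for the same gene, and the median difference of those was 15.4% of the called one.

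The 12 higher genes with the largest differences that kept their direction in both native and nuclear transfer lines began with Ap1m2, a subunit of the epithelial clathrin adaptor (3.53 ± 0.59), AI506816 (2.83 ± 0.30), Eif2s3y (2.79 ± 0.30) and Zfp982 (2.50 ± 0.45). They went on with Gtsf1l, Baiap2l1, the organic anion transporter Slco4a1, Galnt3, which starts mucin-type glycosylation (1.90 ± 0.32), Sdc4, Fam168a, Gdpd1 and the ciliary gene Tmem237 (1.27 ± 0.21). Their adjusted p lay between 9.4e-04 and 0.0495. The 12 lower genes began with Xist (−3.96 ± 0.19), Rpgrip1, Mir1931 (−2.43 ± 0.37) and the peptide transporter Slc15a2 (−2.38 ± 0.27). They went on with the mitochondrial Tmem14c, needed for heme synthesis (−2.01 ± 0.30), Ikbip, Id1, the brain creatine kinase gene Ckb (−1.35 ± 0.24), Gcnt1, which branches O-glycans, Slc35a5, the tRNA methyltransferase gene Trmt1 and Got1l1 (−1.29 ± 0.19), with adjusted p between 1.7e-06 and 0.046. Signals of Rpgrip1 were 2182 to 2881 in the BDF1 lines and 295 to 434 in the CD-1 lines. With a covariate of Y-linked signal the difference of Zfp982 was −0.69, and without the less specific probe sets that of Trmt1 was −0.18. The calls of Xist and Eif2s3y rest on the native lines, where the differences were −7.67 and 4.84, against −0.25 and 0.74 in nuclear transfer lines. Of these 24 calls, 7 held whichever line was left out: AI506816, Eif2s3y, Sdc4, Fam168a, Xist, Rpgrip1 and Slc15a2. The other 17 ended without BDF1 native line 1, and 11 without BDF1 native line 2. The number ended was 12, 15 and 12 without BDF1 nuclear transfer lines 2, 4 and 5, 12 and 1 without CD-1 native lines 1 and 2, and 11 and 15 without CD-1 nuclear transfer lines 3 and 5.

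**Figure D4:**
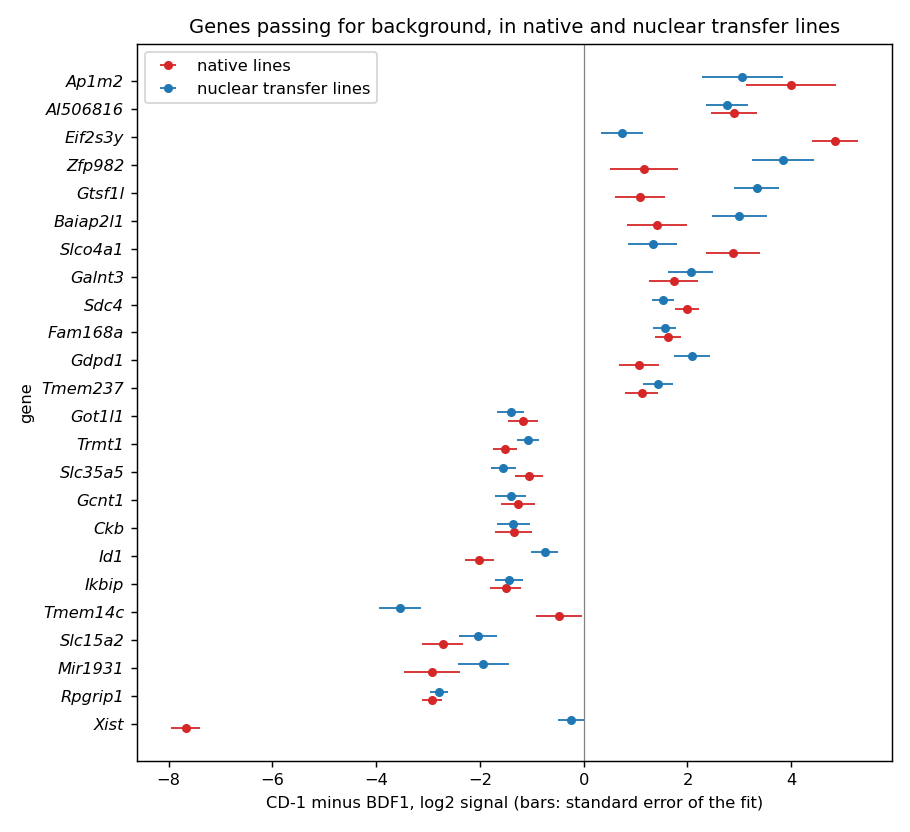
Log2 difference in signal, CD-1 minus BDF1 (horizontal axis), of the 24 named genes that passed for background (vertical axis), shown for native and nuclear transfer lines. Points are fitted differences and bars their standard errors. Xist and Eif2s3y differ by −7.67 and 4.84 in native and by −0.25 and 0.74 in nuclear transfer lines.

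Of 25 glycolysis and hypoxia genes, 23 were lower in CD-1 lines, with a median of −0.43. There were 19 that fell when adjusted over the list alone, among them the glycolytic enzyme genes Ldha (−0.38 ± 0.08), Pgk1 (−0.39 ± 0.10), Tpi1 (−0.42 ± 0.12) and Pfkp (−1.46 ± 0.43), and the hypoxia-induced P4ha1 (−0.77 ± 0.18) and Ankrd37 (−1.01 ± 0.27). None passed over all genes in limma, with 19 at an unadjusted p under 0.05. The list had an adjusted p of 5.2e-14 with camera's preset and an adjusted p = 0.61 with an estimated correlation. That correlation was 0.51, so the value at the preset may be far too small. Its mean deviation was −0.52 to −0.14 in the CD-1 lines and −0.01 to 0.54 in the BDF1 lines other than nuclear transfer line 2, which had −0.23.

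All 22 epithelial genes were higher in CD-1 lines, with a median of 0.46. Adjusted over the list alone 4 rose: the adhesion molecule Epcam (0.54 ± 0.14), Grhl2 (0.75 ± 0.20), the claudin gene Cldn7 (2.00 ± 0.56) and the epithelial factor Elf3 (1.41 ± 0.39). None passed over all genes in limma, with 8 at an unadjusted p under 0.05. The list had an adjusted p of 1.2e-06 with camera's preset and an adjusted p = 0.67 with an estimated correlation. The X inactivation list was lower in 7 of 11 genes (median −0.30, adjusted p = 6.4e-04, and adjusted p = 0.21 with an estimated correlation), with Xist and Utp14a (−0.74 ± 0.16) lower over the list alone. No set test of it was run without Xist here either. Without CD-1 native line 2 the Utp14a difference was −0.89.

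The other 20 lists did not pass for background, with medians from −0.21 to 0.35 and adjusted p between 0.13 and 0.97. The number of passing lists was 6, 6, 10 and 7 without BDF1 native line 2, BDF1 nuclear transfer line 4, CD-1 native line 2 and CD-1 nuclear transfer line 5. Some of their members passed over their list alone. The kinase gene Nrk of spongiotrophoblast rose by 2.54 ± 0.49, Epcam of the syncytiotrophoblast list by 0.54 and Cdkn1c by 1.27 ± 0.27, the last with signals of 4630 and 2930 in the CD-1 native lines, 2064 and 947 in the CD-1 nuclear transfer lines and 657 to 1240 in the BDF1 lines. Over the settings tried, the difference of Nrk ranged from 1.93 to 3.36. The chromatin silencing genes Ezh2, Trim28 and Hdac1 fell by 0.46, 0.38 and 0.51. The check genes Cdx2, Eomes, Elf5, Esrrb, Fgfr2, Hand1, Igf2, Phlda2, Peg3, Meg3, Col1a1 and Gata6 did not pass, with log2 differences between −0.62 ± 0.28 for Gata6 and 1.01 ± 0.50 for Phlda2. Without CD-1 native line 2, which left a lone line in its group, the Esrrb difference was −1.12.

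Background was also compared within each origin. Among native lines it was not separated from the difference in Xist and Eif2s3y, and so from a possible difference in sex. Among native lines 29 probe sets passed, 8 higher and 21 lower, with 1784 at an unadjusted p under 0.05, and among nuclear transfer lines 54, 17 higher and 37 lower, with 2709. Of these, 12 passed in both, all in the same direction. The native count was 9 and the nuclear transfer count 7 without an intensity trend, and with array weights the latter was 106. With the covariate of Y-linked signal the native count was 0. Tmem14c had signals of 14.4 and 44.4 in the CD-1 nuclear transfer lines, against 334 to 383 in those of BDF1 (−3.55), and of 341 and 144 against 317 and 305 in native lines (−0.48). The native count was 71 without CD-1 native line 2 and 15 without CD-1 native line 1, 8 and 16 without BDF1 native lines 1 and 2, 19 and 18 without BDF1 nuclear transfer lines 2 and 5, and 19 without CD-1 nuclear transfer line 5. The count for nuclear transfer lines was 26, 15 and 27 without BDF1 nuclear transfer lines 2, 4 and 5, and 24 and 10 without CD-1 nuclear transfer lines 3 and 5. Without both CD-1 native lines, a setting chosen after the data were seen, it was 63. Over all genes the background differences in native and in nuclear transfer lines, which share no lines, correlated with r = 0.146 across genes and had the same sign in 53.8%. In 822 genes the CD-1 and BDF1 lines did not overlap in either origin, in the same direction, where chance gives 408.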

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

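The tests on the first and second patterns, and those on leaving out CD-1 native line 1, were chosen only after the results were seen, while the test of scaling on the 3 lists was chosen before. The origin difference itself differed between CD-1 and BDF1 for 4 probe sets, by a test of the interaction. It was 7.43 and 5.67 log2 units larger in CD-1 for 2 probe sets of Xist, and −3.93 for Tmem87a and −3.14 for a probe set of Psmd6. For Tmem87a and Psmd6 no explanation was tested.

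The CD-1 native lines had low Xist signal (5.35 and 1.28, and 15.9 and 27.5 in another called probe set) and high Eif2s3y signal, and the other 7 lines showed the opposite. The tables argue against a loss of Xist with both X chromosomes active, since the median background difference among native lines of X-linked genes exceeded that of autosomal genes by 0.0351 (95% bootstrap interval −0.0237 to 0.0868). That 0 of the 7 other lines had Eif2s3y above 100 follows from the pattern itself, so an exchange of labels between the CD-1 groups stays open. A Y chromosome in these lines may explain the pattern: the mean log2 signal of the 4 Uty probe sets was 5.55 and 4.83 there, a level 0 of the 7 other lines reached (2.69 to 3.27), although the Uty probe sets lay below the filter, and other Y-linked genes did not add to this, since Uba1y did not pass within CD-1 (−0.14 ± 0.48) and the 3 Kdm5d probe sets, all below the filter, had means between 2.84 and 3.98 in the other lines, with both CD-1 native lines inside that range. A single X chromosome stays open, as 5 genes that escape X inactivation were higher on average in CD-1 nuclear transfer lines by 0.365 ± 0.0967. In BDF1 ones they were also higher, by 0.327 ± 0.118, a control added after the first value was seen. Here ± is the standard error over the 5 genes and holds no spread between lines. The sex of the lines, which the labels do not give, is not separated from origin within CD-1 or from background among native lines. The averaged comparisons and the interaction contain these differences.

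Many background calls rested on 1 probe set of a gene. For 57 called probe sets with others of the same gene, the others showed a median of 15.4% of the called difference (95% interval 10.7 to 41.2), with 34 under 33% and 12 of opposite sign. This is consistent with sequence variants between CD-1 and BDF1 under the probes of single probe sets, and isoform use, 3′ end use and the selection of the called probe set, which lowers this share by itself, stay open. The tables argue against the scaling between arrays as the cause, since 87.6% of the 97 probe sets passed in the same direction after quantile normalization. A difference in expression between the backgrounds was not excluded for any of these probe sets and stays open, also for the 12 whose others showed at least 67% of it and for those without others.

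The epithelial, interferon and FGF lists differed by origin, and CD-1 native line 1 lay farthest from the mean in each. Without that line the epithelial median kept 90.0% of its value, which argues against this line as its cause, and the FGF and ERK median kept 28.2%, so that this line may account for most of that difference. For the interferon list, which kept 57.4%, the share of this line cannot be told apart from that of origin. Scaling between arrays is argued against, as after quantile normalization the lowest of the 3 medians kept 96.7% of its value. An effect of nuclear transfer on these lists did not hold in a test with an estimated correlation and stays open, as does a different cell state of this line, where the TS stem state list was also lowest (−0.68, against −0.00068 to 0.21 in the other lines).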

How the results depend on the processing

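Leaving out both CD-1 native lines was chosen only after the results were seen, and all other settings before. Among counts and correlations, 172 values stayed within 1.5 times or 1 SD of the reported one and 90 did not, and of the values for single genes and lists, 2769 kept their direction and call, 302 lost the call, 25 gained one and 54 turned their direction, most of them differences that passed neither before nor after. Median centring moved no count by more than 1.5 times, and neither did leaving out the filter. For the differences in correlation between lines 1 SD of the pairs (0.0118) exceeds the differences themselves, so this bound says nothing on their stability. Over 8 settings, of which median centring cannot change a correlation, they ranged from 0.00289 to 0.0109 for background and from 0.00147 to 0.0057 for origin. For the changes below the cause was not tested, except where fewer features or lines were used.

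With no pseudocount, the number of passing probe sets was 4 for origin, 8 for origin in CD-1 and 18 for background in native lines. A pseudocount 4 times larger gave 1 for origin in BDF1, 7 for the interaction and 8 lists for the interaction. A stricter filter gave 10 for origin in CD-1. Quantile normalization gave 5 lists for the interaction. Without an intensity trend the counts were 2 for origin, 6 for origin in CD-1, 34 for background, 9 for it in native lines and 7 in nuclear transfer lines. Robust variances gave 28 for origin in CD-1, and array weights 106 for background in nuclear transfer lines. An additive model gave 0 for origin and 64 for background, as did leaving the other factor out (0 and 64). Without X and Y genes, which removes calls by construction, the counts were 3 for origin, 8 for origin in CD-1 and 2 for the interaction. With the mean over probe sets, and so fewer features, they were 3 for origin, 5 for origin in CD-1, 2 for the interaction, 19 for background, 2 in native lines, 14 in nuclear transfer lines, and 6 lists for the interaction. Trmt1 had a background difference of −0.18 without the less specific probe sets. Small differences that did not pass turned in sign: for origin, Elf5 was −0.25 with the mean over probe sets and Fgfr2 0.0088 without the less specific ones. For background, Eomes was 0.0022 with a pseudocount 4 times larger, 0.000405 with quantile normalization, 0.023 with array weights and 0.0018 in an additive model, Igf2 was 0.0069 with the other factor left out, and Meg3 −0.018 with no pseudocount.

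A covariate of Y-linked signal was added to the 4 group means, so its slope came only from differences within groups. The largest were among BDF1 nuclear transfer lines, at mean log2 signals of 3.08, 3.10 and 3.72, against 6.29 and 6.30 in the CD-1 native lines. The values with it therefore do not show whether Y-linked signal accounts for a difference. The covariate, which separates the CD-1 native lines from the rest by construction, gave 0 for origin, origin in CD-1, the interaction, background and background in native lines, with 7 lists for background and 6 for the interaction. Under it the syncytiotrophoblast list for origin had a median of −0.11 with the set test turned upward, the TGF-beta list for the interaction −1.37, and Zfp982 for background −0.69. Differences that passed in neither fit also turned: for origin Syne4 (0.023), Tmem54 (0.73), Galnt3 (0.22), Hand1 (−0.24), Peg3 (−0.52) and Meg3 (−2.79), and for background Igf2 (5.67).

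Lines of different groups share numbers. Same-numbered lines had correlations of their deviations of −0.186 for native lines of both numbers, a single value since deviations mirror each other in groups of 2, and of −0.152, −0.0018 and 0.032 for the other pairs. They give no sign that the numbers pair the lines. A fit with the number as a block had almost no residual degrees of freedom, and lines that alone held a number were fitted exactly. Its values therefore say little on the stability of the results. With the number as a block, the counts were 0 for origin, 0 for origin in CD-1, 0 for the interaction, 7 for background, 5 in native and 2 in nuclear transfer lines, and 6 lists for the interaction. The p53 list for origin had a median of 0.024, and Igf2 for background a difference of 2.11 with the block (adjusted p = 0.013), against −0.19 without it and adjusted p up to 0.998 over all settings. Differences that passed in neither fit turned with the block for origin in Kdm6a (−0.016), Myc (−0.057), Atf4 (−0.12), Trib3 (−0.32), Fgfr2 (0.017), Tfap2c (−0.67), Hand1 (−0.30), Igf2 (2.21) and Meg3 (−0.50), and for background in Eomes (0.17) and Meg3 (−1.63).

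With an estimated correlation, 0 lists passed for origin, 0 for background and 0 for the interaction, against 8, 3 and 3 with the preset, and by fry 1 list passed for each, that of X inactivation. That list holds Xist, and no set test of it was run without Xist. For the interaction its median was 0.075, and Xist was the only member that passed over the list alone.

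With 1 line left out, the lone line of a group was assumed to vary like the others. Such a group adds nothing to the estimate of spread, so calls gained in these fits do not support a difference. The counts ranged from 3 to 38 for origin, 0 to 2 for origin in BDF1, 7 to 101 for origin in CD-1, 3 to 8 for the interaction, 41 to 167 for background, 8 to 71 in native lines and 10 to 64 in nuclear transfer lines. The lists ranged from 8 to 10 for origin, 3 to 10 for background and 1 to 10 for the interaction. The highest were without CD-1 native line 2, except for origin in BDF1, background in nuclear transfer lines and the lists for origin. Some differences changed sign without 1 line, none of them passing after the change. For origin these ranged from −0.26 to 0.66 for Cdx2, −0.074 to 0.60 for Elf5, −0.21 to 0.036 for Fgfr2, −0.075 to 0.33 for Peg3 and −1.27 to 1.83 for Meg3. For background they ranged from −0.38 to 0.38 for Eomes, −0.47 to 0.20 for Elf5, −1.12 to 0.14 for Esrrb, −1.03 to 0.65 for Igf2, −0.10 to 0.30 for Peg3 and −1.50 to 1.60 for Meg3. Without both CD-1 native lines 63 probe sets passed for background in nuclear transfer lines, 49 of them among the 54, and 0 for origin in BDF1. Signals near the pseudocount of 5.53 carry little information, which limits what can be said of dim genes.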

Other observations

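The tests on the spread of imprinted genes were chosen only after the result was seen, and the counts of other splits before. The number of probe sets that passed for origin was 7, and the highest count among other splits of the lines within each background was 14. Of 60 splits, 9 gave as many, the real one included, so chance is not excluded. Of these 9, 8 kept the CD-1 native lines apart from the CD-1 nuclear transfer lines, as 20 of the 60 splits do, and 1 was among the 40 that do not. The splits thus retain the CD-1 difference, from which the 7 calls come, and say little on chance within CD-1. For background the number was 97 and the highest other 9, and 1 of 60 splits of the lines within each origin gave as many, the real one. The real split thus ranked first, but 1 of 60 is the smallest share these splits can give, so chance is made unlikely and not excluded. The splits say nothing on any single call.

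Imprinted genes varied strongly between lines of a group. Their median SD within groups was 0.714 over 51 genes, against 0.330 for random lists of like signal, at a percentile of 100 (permutation p = 1e-04, the smallest the 10000 lists can give). Of 23 lists tested, 16 had an adjusted p under 0.05, so a large spread was not specific to imprinted genes. A greater spread between nuclear transfer than between native lines was not shown, with the ratio at a percentile of 94.6.

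Some genes chosen after their values were seen were nearly absent from single lines. Kcnq1ot1, a paternally expressed noncoding RNA, had a signal of 1.91 in CD-1 native line 2 and of 217 to 489 in the others. The lipid carrier gene Apoe had 4.29 in BDF1 nuclear transfer line 2, 7.46 in CD-1 native line 1 and 25.0 in CD-1 nuclear transfer line 5, against 323 to 730 in the others.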
